A study of Homo sapiens with 12 samples.

How the data were processed

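RNA sequencing was done on cultured HCC-LM3 and Huh-7 liver cancer cells, wild type and METTL5 knockout. Per the labels' protocols, wild-type cells were untreated, knockout cells were made with a guide RNA against METTL5, total RNA was extracted with TRIzol, libraries were made from 1 µg of RNA and sequencing was done on an Illumina NovaSeq. The labels name no control guide, clone, culture or batch. Groups and replicate numbers were taken from the sample labels, which gave 12 libraries in 4 groups of 3.

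The authors deposited 1 table of 58884 Ensembl genes with an expected count and a TPM value per library and a gene length, per the file headers. The expected counts the authors deposited are not normalized and 7.49% to 13.3% of the values in a library are not whole. The deposited TPM values are the authors' length-scaled values and sum to 977632 to 998831 per library. They were used only to check a few genes. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse builds mm8 and mm9 were named, which do not go with human Ensembl identifiers. The counting tool, its strand setting, the annotation release and the human build are not given in the sources used here. How reads that map to several genes were shared out is therefore unknown, so genes with near-identical copies or overlapping neighbours are uncertain. All per-sample columns were matched to a sample by name.

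Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups, which left 16537. Libraries were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group was fitted to all 12 libraries together (8 residual degrees of freedom). The contrasts were knockout minus wild type in each line, the HCC-LM3 effect minus the Huh-7 effect, and wild-type HCC-LM3 minus wild-type Huh-7. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and all tests were two-sided. The standard error of a log2 fold change was taken from its F statistic. Overlaps of called genes between the lines were tested with Fisher's exact test. With 3 libraries against 3, an exact permutation test of 1 gene cannot go under p = 0.1. The TMM factors were 1.33 to 1.51 in HCC-LM3 wild type, 1.27 to 1.31 in its knockout, 1.06 to 1.10 in Huh-7 wild type and 0.491 to 0.51 in its knockout.

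Coordinates, gene types, transcript GC content and transcript lengths came from GENCODE 29 on GRCh38, in which 99.54% of the gene identifiers were found. Symbols were current gene symbols, or the deposited names where there was none. The gene length used for the offsets was the deposited one. GC content and length were known for 16480 of the tested genes (99.7%). The 30 gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, for lists with at least 5 tested members, and p-values were adjusted over the lists. The lists covered fatty acid uptake and activation, beta-oxidation, fatty acid synthesis, cholesterol synthesis, triglyceride and lipoprotein handling, m6A and rRNA methylation, small-subunit and large-subunit ribosomal proteins, ribosome biogenesis, translation factors, the integrated stress response, the unfolded protein response, p53 targets, mitosis, DNA replication, epithelial, mesenchymal, matrix, hepatocyte and xenobiotic genes, hypoxia and glycolysis, oxidative phosphorylation, antioxidant response, interferon, NF-kappaB, immediate early genes, Wnt, YAP and Notch targets, apoptosis, mitochondrially encoded mRNAs and histones. The 5 sets of cell type markers were given as summed levels. For a gene at 0 counts in a whole group, a fold was given only as a bound, against a floor of 3 counts per library.

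Groups, tests, lists, marker sets, the rule for named genes and most alternatives were fixed before the data were examined. The rule named METTL5, TRMT112 and the ACSL genes throughout. For each knockout it took the 8 largest increases and 8 largest decreases among called protein-coding genes with a mean of at least 5 CPM and no overlap between knockout and wild-type values. It took 6 genes per direction changed in both lines, 3 per sign changed in opposite directions, 5 per direction between the wild-type lines, and up to 4 called members of each list with a mean of at least 1 CPM. Genes of the Y chromosome and of X inactivation were not named. Many genes the rule takes from the lists are left out of the text, whether or not their call ended under an alternative, and a few genes the rule takes are not reported here and were not replaced.

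The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter and a stricter filter on low counts (at least 1 CPM in 3 libraries), each line fitted alone, the replicate number as a block, stricter thresholds, the other list tests and leaving out each library in turn. Added after the data had been seen were offsets for GC content and gene length (a spline with 5 degrees of freedom for each, from log2 CPM with a prior count of 2), library totals alone without composition factors, thinning to the lowest library total, leaving out the 50 most abundant genes, leaving METTL5 out of the gene list that holds it, and leaving ENO1, LDHA, PKM and TPI1, which have uncertain counts, out of the hypoxia and glycolysis list. A lower pseudocount had been listed for normalized values and does not apply to counts.

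The test was tried on simulated counts with the real mean of each line, genotypes pooled, and the real library sizes. The 200 changed genes were drawn from genes with a mean of at least 5 CPM, so recovery at lower levels was not tried. At 1.5-fold, 2-fold and 4-fold, it recovered 73.1%, 94% and 98.5% in HCC-LM3 and 67.2%, 94% and 98.5% in Huh-7 (16179 genes). For the difference between lines it recovered 31.3%, 77.6% and 97% (16229 genes). Of 15979 unchanged genes, 10 and 13 were called in the lines. Few genes changed in this simulation, so these numbers may not hold for Huh-7, where 12399 of 16537 genes were called. With a GC and length trend added to the simulated counts, 66.01% of unchanged genes were called without offsets and 0.4% with them. The added trend had the form that the offsets fit, so trends of another form were not tried. With no list changed, camera called 0 of 30 lists. The simulated genes varied independently, so this does not show how often camera calls lists of correlated genes. No pair of replicates differed by less than counting noise, so all 12 libraries counted.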

Results

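Gene expression was measured by RNA sequencing in human liver cancer cell lines with and without METTL5. METTL5 is a methyltransferase that places an m6A mark on the RNA of the small ribosomal subunit, and TRMT112 is the protein it pairs with. HCC-LM3 is a hepatocellular carcinoma line with high metastatic capacity, and Huh-7 is a hepatocellular carcinoma line that keeps many hepatocyte traits. Each line was sequenced as untreated wild-type cells and as cells that received a guide RNA against METTL5, which gave 4 groups of 3 libraries. Summed over genes, the libraries held 17495275 to 26415496 counts. The mean was 23723973 ± 1987045 in HCC-LM3 wild type, 24794576 ± 2368825 in HCC-LM3 knockout, 21702425 ± 3712965 in Huh-7 wild type and 18625302 ± 1653661 in Huh-7 knockout (SD, n = 3 each). The labels number the replicates without saying that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Levels are given as CPM, counts relative to library size after trimmed-mean (TMM) scaling, unless stated otherwise. Floors cover counting error only, while SD and SE values include the spread between libraries.

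The first question was whether the targeted gene was lost. METTL5 (ENSG00000138382) lies on chromosome 2 from 169810081 to 169824931 on the minus strand of GRCh38, and its end overlaps SSB, which lies on the other strand. It was at 0 counts in all 6 knockout libraries. The wild-type libraries held 268, 327 and 325 counts in HCC-LM3 and 237, 258 and 169 in Huh-7, or 8.99 ± 0.814 and 9.51 ± 1.55 CPM (SD, n = 3). Against a floor of 3 counts per library, METTL5 was at least 86.9-fold lower in HCC-LM3 knockout and at least 27.2-fold lower in Huh-7 knockout. Of 8109 genes with at least 100 counts in every wild-type library, METTL5 was the 1 gene at 0 in all 6 knockout libraries. TRMT112 did not pass the test in HCC-LM3, with a log2 fold change of 0.15 (SE 0.11, adjusted p = 0.335, edgeR). Without wild-type replicate 1 it did, at 0.30 (adjusted p = 0.00251, the lowest of 23 alternatives, of which the highest gave 1). In Huh-7 TRMT112 rose by 2.0 (SE 0.11, adjusted p = 3.82e-17), and by 0.97 with offsets for GC content and gene length (adjusted p = 6.11e-12, range over 23 alternatives 6.85e-88 to 1.13e-08).

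**Figure D1:**
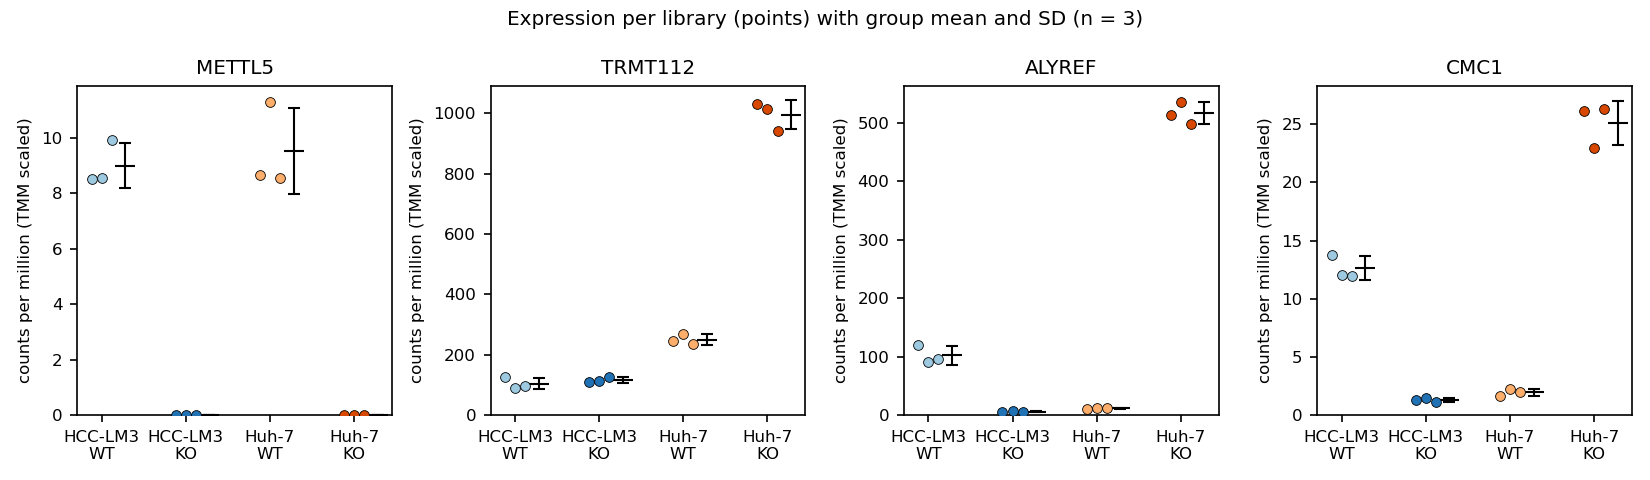
Levels of METTL5, TRMT112, ALYREF and CMC1 in CPM (vertical axis) in the 4 groups, with a point per library and bars for the mean and SD of 3 replicates. METTL5 is at 0 in all 6 knockout libraries, and ALYREF goes from 102 to 5.82 CPM in HCC-LM3 and from 11.7 to 516 in Huh-7.

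The second question was how HCC-LM3 knockout cells differed from wild type. Wild-type cells were untreated, and no control guide or clone is named. In either line, METTL5 loss therefore cannot be told from effects of the guide treatment or of clones. The lists of ATF4 and integrated stress response targets, immediate early genes and mesenchymal genes were higher in the knockout, with 20 of 34, 16 of 24 and 13 of 25 members risen. The lists of mitotic genes, ribosome biogenesis factors and cholesterol synthesis enzymes were lower, with 18 of 36, 22 of 56 and 9 of 25 fallen, while 4 and 3 of the last pair rose. These calls used camera at a preset correlation. With an estimated correlation the mesenchymal list alone passed (adjusted p = 0.0114), and the other 5 had adjusted p = 0.133, 0.0641, 0.0641, 0.295 and 0.313 in the order given. After METTL5, the strongest fall among the genes named for this line was that of ALYREF, an mRNA export adaptor, which went from 102 ± 15.8 to 5.82 ± 0.742 CPM (log2 fold change −4.13, SE 0.12, adjusted p = 1.24e-22, n = 3). In edgeR's quasi-likelihood test, 4440 of 16537 tested genes differed at an adjusted p under 0.05, of which 2308 were higher and 2132 lower in the knockout. An absolute log2 fold change of at least 1 was reached by 282 of them, 144 higher and 138 lower. The count was 6136 without wild-type replicate 1, 2832 without wild-type replicate 2 and 2743 without wild-type replicate 3. With library totals alone in place of TMM factors, which moved the median gene by −0.16, the split was 1199 higher and 3423 lower.

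Among the single genes, RBM15, a subunit of the m6A writer complex of mRNA, rose from 8.59 ± 1.27 to 26.1 ± 1.17 CPM (1.60, SE 0.13, adjusted p = 2.74e-10). ABCG1, a cholesterol exporter, rose by 1.53 (SE 0.20, adjusted p = 2.6e-06), and PCDH1, SHC2 and KREMEN2 by 1.25, 1.16 and 1.16. The complement genes C4A and C4B had values of 1.51 and 1.25, but they are near-identical copies and the split of reads between them is uncertain. On the lower side, CMC1, a mitochondrial protein of cytochrome oxidase assembly, followed ALYREF at −3.28 (SE 0.17, adjusted p = 6.75e-16). PDK4, the kinase that shuts off pyruvate dehydrogenase, fell by 1.68 (SE 0.15, adjusted p = 3.05e-09). The guanine deaminase GDA, the integrin activator FERMT2, CIPC, LRRC58 and KIAA1143 also fell, with −1.46, −1.46, −1.45, −1.40 and −1.21. RBM15, ABCG1, C4A, C4B, SHC2, KREMEN2, FERMT2, CIPC, ALYREF and CMC1 overlap other annotated genes, and no strand setting is given, so reads of the partners may be mixed.

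The integrated stress response list had 34 tested members, of which 20 rose and none fell (adjusted over the list alone, 22 rose and 1 fell). Its median log2 fold change was 0.38 and its camera adjusted p = 1.51e-09 at a preset inter-gene correlation of 0.01, and the adjusted p = 0.133 with an estimated correlation. PHGDH, the first enzyme of serine synthesis, rose by 1.16 (SE 0.11, adjusted p = 1.06e-08). The stress cytokine GDF15 rose by 0.95, the leucine sensor SESN2 by 0.93 and the glutathione-degrading enzyme CHAC1 by 0.89. Among 24 immediate early and MAPK feedback genes, 16 rose and none fell (17 and 0 adjusted over the list alone; median 0.44, adjusted p = 1.51e-09, and adjusted p = 0.0641 with an estimated correlation). The AP-1 subunits JUN and FOSL1 rose by 0.84 and 0.74, IER3 by 0.84 and the ERK-responsive factor ETV5 by 0.68. Of 25 mesenchymal and invasion genes, 13 rose and 1 fell (13 and 3 adjusted over the list alone; median 0.33, adjusted p = 1.47e-06). This was the 1 list that also passed with an estimated correlation, at adjusted p = 0.0114. Its members included the integrins ITGB3 and ITGA5 at 1.30 and 0.89, the secreted matrix protein TGFBI at 1.03 and the urokinase gene PLAU at 0.89.

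Of 27 NF-kappaB and acute-phase genes, 10 rose and 1 fell, the same counts as adjusted over the list alone (median 0.42, adjusted p = 0.00428, and adjusted p = 0.0641 with an estimated correlation). SOCS3 rose by 0.72 and the adhesion molecule ICAM1 by 0.67, and the median was 0.24 with GC and length offsets. Among 35 extracellular matrix genes, 10 rose and 2 fell over all genes and over the list alone (median 0.17, adjusted p = 0.0293, and adjusted p = 0.313 with an estimated correlation). AGRN rose by 0.78 and TIMP3 by 0.72, while LAMA1 fell by 0.70. The offsets put SOCS3 at 0.43 and AGRN at 0.46. The call of this list ended with offsets for GC content and gene length (median 0.05, adjusted p = 0.47), without wild-type replicate 1 (adjusted p = 0.122) and without knockout replicate 2 (adjusted p = 0.0548). The range over 16 alternatives was 0.0159 to 0.47.

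Among 36 mitotic genes, 18 fell and none rose (20 and 3 adjusted over the list alone; median −0.41, adjusted p = 1.82e-06, and adjusted p = 0.0641 with an estimated correlation). The spindle checkpoint kinase BUB1 fell by 0.86 (SE 0.11, adjusted p = 1.59e-06) and the centrosome kinase NEK2 by 0.77. Offsets for GC content and gene length took the median to −0.19 and the number that fell to 11 (adjusted p = 0.000943). Of 56 ribosome biogenesis factors, 22 fell and 4 rose (26 and 5 adjusted over the list alone; median −0.22, adjusted p = 0.000217, and adjusted p = 0.295 with an estimated correlation). RIOK2 fell by 1.01, the nucleolar helicase DDX21 by 0.86, RIOK1 by 0.86 and LTV1 by 0.78. The same offsets put RIOK2 at −0.66, DDX21 at −0.54 and LTV1 at −0.49. Of 25 cholesterol synthesis genes, 9 fell and 3 rose (11 and 3 adjusted over the list alone; median −0.23, adjusted p = 0.0044, and adjusted p = 0.313 with an estimated correlation). CYP51A1 fell by 0.79 and IDI1 by 0.73 (−0.47 each with these offsets), and the call of the list ended without wild-type replicate 1 (adjusted p = 0.0864, range over 16 alternatives 8.73e-05 to 0.0864).

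The m6A and rRNA methylation machinery had 31 members, of which 10 fell and 2 rose (11 and 2 adjusted over the list alone; median −0.12 with METTL5 at its bound, adjusted p = 0.0137, and adjusted p = 0.0758 with an estimated correlation). METTL5 itself is in this list and among those that fell. Without it 9 of 30 fell and 2 rose, the median was −0.11 and the call ended (adjusted p = 0.136, and adjusted p = 0.295 with an estimated correlation); library totals alone gave adjusted p = 0.0336 and GC and length offsets 0.51. YTHDC2 and METTL14 fell by 0.91 and 0.90, against the rise of RBM15, with YTHDC2 at −0.60 under GC and length offsets. Large-subunit ribosomal protein genes rose in 12 of 46 cases and fell in none, the same adjusted over the list alone (median 0.16, adjusted p = 0.00387, and adjusted p = 0.75 with an estimated correlation), with RPL13 at 0.55 and RPL28 at 0.48 (0.30 each with the offsets). Small-subunit genes rose in 3 of 32 cases and fell in none (2 and 0 adjusted over the list alone; median 0.15, adjusted p = 0.0137, and adjusted p = 0.75 with an estimated correlation). Both ribosomal calls ended with library totals alone, at medians of 0.01 and 0.00 and adjusted p = 0.0726 and 0.147. Without wild-type replicate 2 the large-subunit list had adjusted p = 0.106 (range over 16 alternatives 4.64e-09 to 0.106). The small-subunit list had adjusted p = 0.208 without wild-type replicate 2, 0.111 without wild-type replicate 3 and 0.0969 without knockout replicate 3 (range 2.36e-07 to 0.208).

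Of the pair of lists that track library quality, mitochondrially encoded mRNAs rose in 7 of 13 cases and fell in none, the same adjusted over the list alone (median 0.31, adjusted p = 0.00299, and adjusted p = 0.385 with an estimated correlation), with MT-ND1 at 0.49. Replication-dependent histones, whose mRNAs lack a poly(A) tail, rose in 5 of 32 cases and fell in none (4 and 0 adjusted over the list alone; median 0.46, adjusted p = 0.015, and adjusted p = 0.295 with an estimated correlation), with H1-2 at 1.06 and H2BC8 at 0.89. The knockout libraries also held more counts from GC-rich genes. Over counts of protein-coding genes outside the mitochondrial genome, the mean transcript GC content was 53.4% ± 0.35 in wild type and 54.3% ± 0.06 in knockout. Genes under 38% GC had a median log2 fold change of −0.41 and genes over 62% GC one of 0.31. With offsets for GC content and gene length 2950 genes passed the test, of which 2121 had passed before with the same sign.

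**Figure D2:**
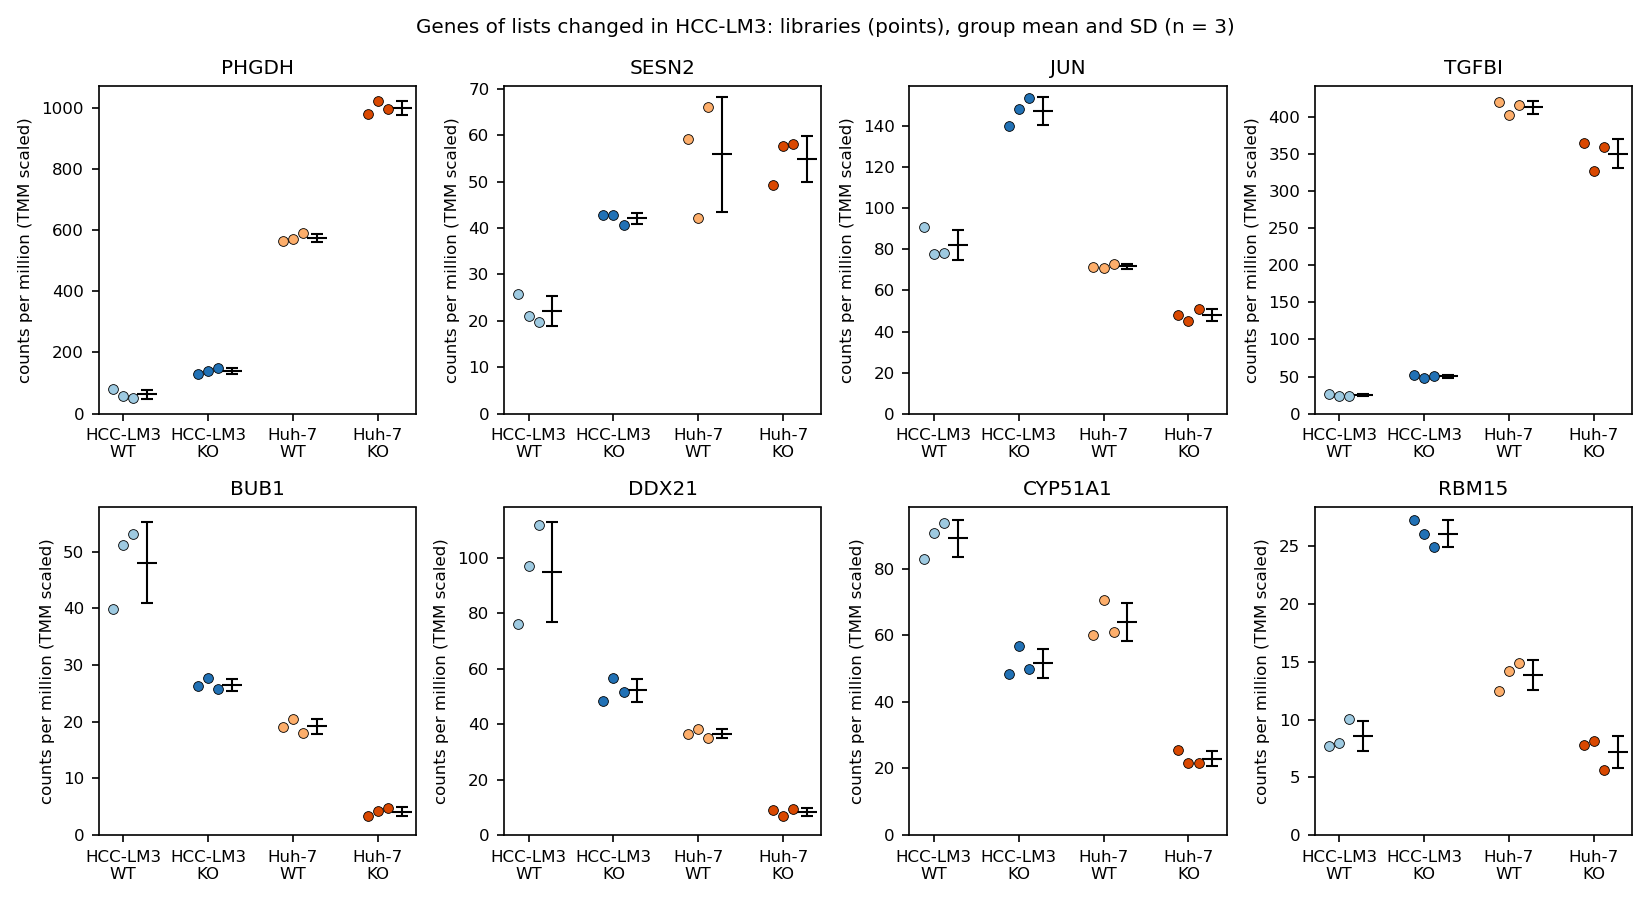
CPM (vertical axes) of PHGDH, SESN2, JUN, TGFBI, BUB1, DDX21, CYP51A1 and RBM15 in the 4 groups, with a point per library and bars for the mean and SD of 3 replicates. In HCC-LM3, PHGDH, SESN2, JUN, TGFBI and RBM15 are higher in the knockout and BUB1, DDX21 and CYP51A1 lower.

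The other 17 lists did not pass the test in HCC-LM3 with TMM scaling and all libraries. For fatty acid uptake and acyl-CoA activation, 4 of 19 members rose and 4 fell (4 and 5 adjusted over the list alone; adjusted p = 0.524), with the transporter SLC27A1 up by 0.73. For beta-oxidation, 8 of 32 rose and 5 fell (11 and 5; adjusted p = 0.31), with ACADS at 0.85 and ACADVL at 0.58. For fatty acid synthesis, 6 of 27 rose and 3 fell (6 and 3; adjusted p = 0.675), with SREBF1 at 0.75 and HACD2 at −0.63. Under GC and length offsets SLC27A1 was at 0.47, ACADVL at 0.38 and SREBF1 at 0.48. For triglyceride and lipoprotein handling, 7 of 29 rose and 2 fell (7 and 2; adjusted p = 0.148), and the list passed as higher with library totals alone (adjusted p = 0.0453, range over 16 alternatives 0.0453 to 0.375). ACSL4, which activates arachidonic acid, fell by 0.53 (SE 0.14, adjusted p = 0.00809), but not with GC and length offsets (−0.25, adjusted p = 0.0928, range over 23 alternatives 2.93e-05 to 0.0928) or without wild-type replicate 3 (−0.39, adjusted p = 0.0646). ACSL3 fell by 0.58 (SE 0.11, adjusted p = 0.000165), and by 0.27 with GC and length offsets (adjusted p = 0.0226, the highest of 23 alternatives, of which the lowest gave 5.84e-06). ACSL1 had −0.27 (SE 0.13, adjusted p = 0.128), but −0.42 (adjusted p = 0.0194, range over 23 alternatives 0.0194 to 0.385) with library totals alone. ACSL5 rose by 0.56 (SE 0.20, adjusted p = 0.0309), a call that ended without wild-type replicate 1, 2 or 3 or knockout replicate 1 or 3 (range over 23 alternatives 0.00523 to 0.252). The ACSL5 call also ended with the replicate block, with each line fitted alone and with library totals alone (adjusted p = 0.0612, 0.0619 and 0.149).

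In the remaining lists, numbers that rose and fell are again followed by those adjusted over the list alone. They were 8 and 13 of 45 translation factors (8 and 14; adjusted p = 0.52), 3 and 2 of 24 genes of the endoplasmic reticulum unfolded protein response (3 and 2; adjusted p = 0.73) and 3 and 4 of 24 p53 targets (3 and 4; adjusted p = 0.856). DNA replication genes had 13 and 8 of 41 (14 and 10; adjusted p = 0.385), epithelial genes 6 and 0 of 23 (5 and 0; adjusted p = 0.144) and hepatocyte genes 3 and 2 of 34 (3 and 2; adjusted p = 0.224), with complement C3 up by 0.73. Xenobiotic genes had 2 and 4 of 25 (2 and 2; adjusted p = 0.856), hypoxia and glycolysis genes 14 and 5 of 37 (17 and 9; adjusted p = 0.315; 14 and 4 of 33 and adjusted p = 0.102 without ENO1, LDHA, PKM and TPI1, whose counts are uncertain), with the hypoxia marker CA9 at 1.14, and oxidative phosphorylation genes 7 and 5 of 48 (7 and 5; adjusted p = 0.581). Without wild-type replicate 1 the last list passed as higher (adjusted p = 0.00883, the lowest of 16 alternatives, of which the highest gave 0.833). Antioxidant genes had 10 and 6 of 33 (10 and 7; adjusted p = 0.516), with HMOX1 at 0.90 and the lipoxygenase ALOX5 at 1.38. Interferon-stimulated genes had 8 and 5 of 40 (8 and 5; adjusted p = 0.73), Wnt, YAP and Notch targets 5 and 2 of 28 (5 and 2; adjusted p = 0.206) and apoptosis regulators 1 and 7 of 30 (1 and 7; adjusted p = 0.206), with BIRC2 at −1.0. When scaled by library totals alone, more members fell than rose in 7 lists where more had risen: 4 and 8 for beta-oxidation, 5 and 8 for fatty acid synthesis, 2 and 9 for the unfolded protein response, 8 and 15 for DNA replication, 6 and 15 for oxidative phosphorylation, 8 and 12 for antioxidant and 5 and 10 for interferon-stimulated genes. In 5 of the 17 lists the signs of the median, the mean and the test were not all the same, and in none of the lists that passed.

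**Figure D3:**
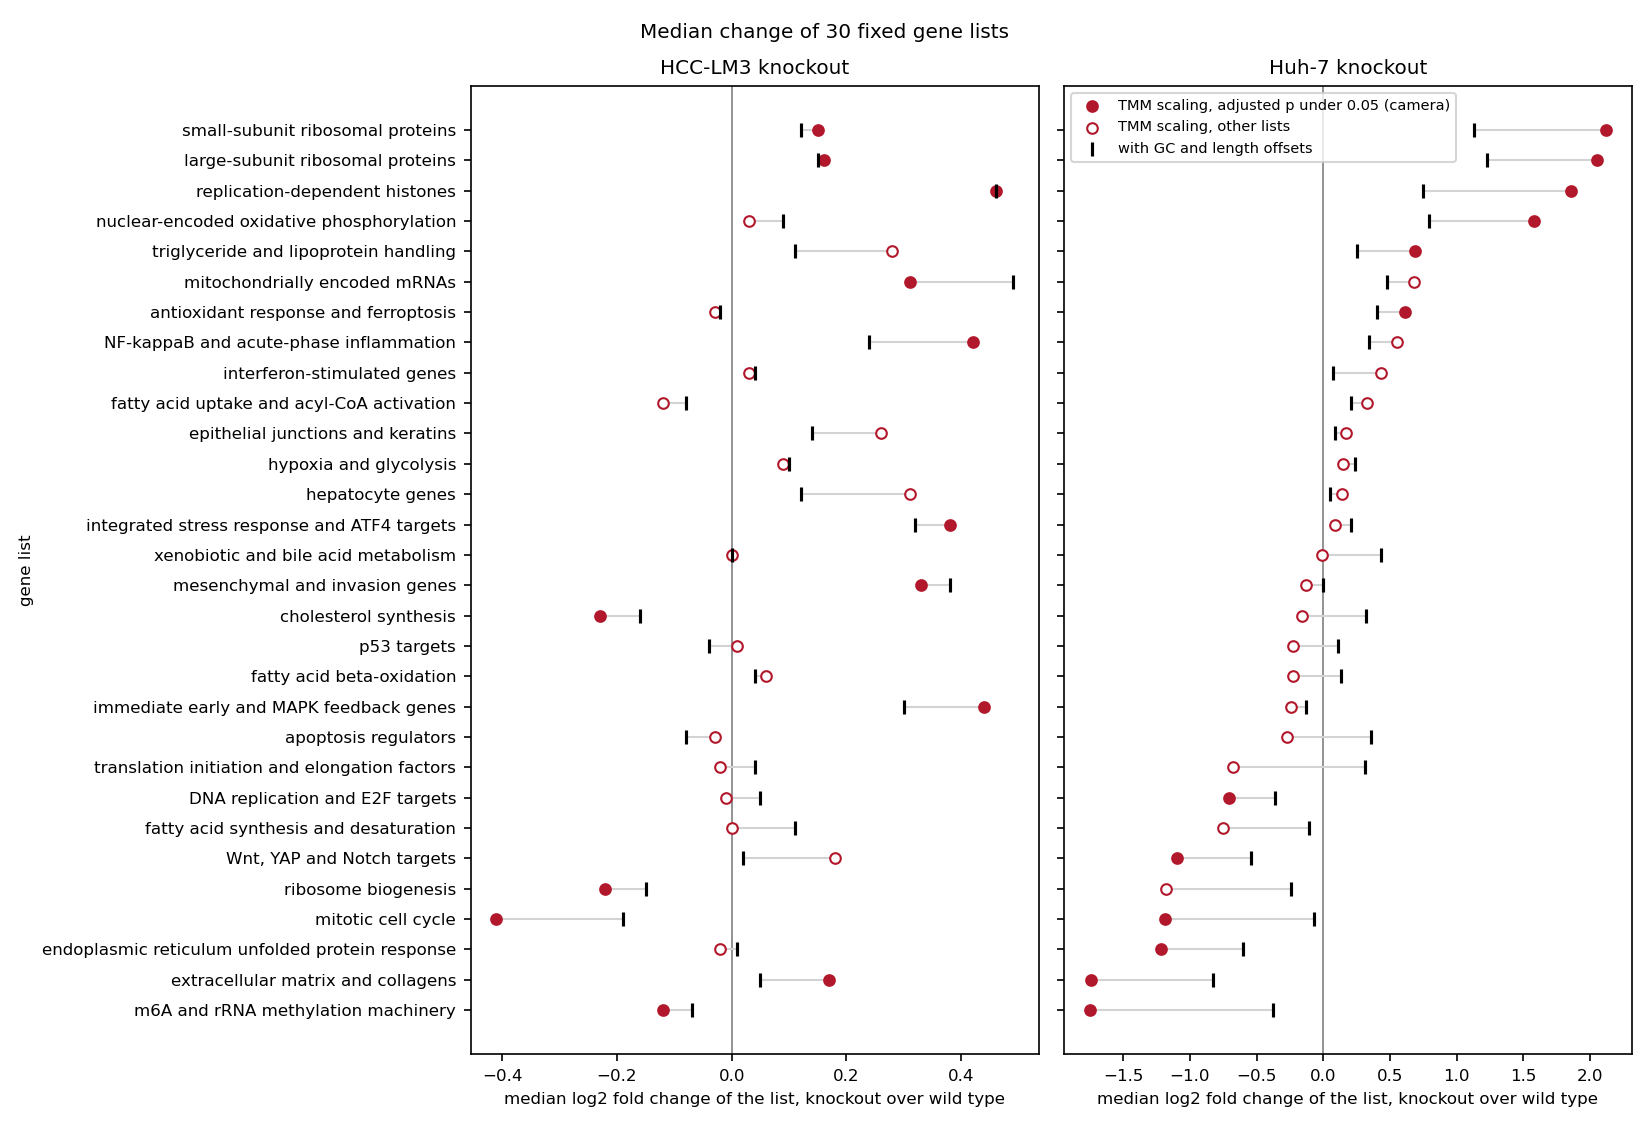
Median log2 fold change of knockout over wild type (horizontal axes, on separate scales) for the 30 gene lists in each line. Filled circles passed the camera test at an adjusted p under 0.05, open circles did not, and black ticks give the median with GC and length offsets; in Huh-7 the ribosomal protein medians go from 2.05 and 2.12 to 1.23 and 1.13.

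The same question in Huh-7 gave a far wider change. Most genes for cytosolic ribosomal proteins and for oxidative phosphorylation, which have short and abundant mRNAs, were higher in the knockout. Risen were 32 of 32 small-subunit, 45 of 46 large-subunit and 40 of 48 oxidative phosphorylation genes, while 6 of the last fell. The ferritin light chain FTL and the glutathione peroxidases GPX1 and GPX4 were higher too, from an antioxidant list with 20 of 33 risen and 9 fallen. The lists of matrix genes, Wnt, YAP and Notch targets and the unfolded protein response were lower, with 26 of 35, 18 of 28 and 17 of 24 fallen and 3, 4 and 7 risen. No list passed with an estimated correlation (lowest adjusted p = 0.156), and the Wnt and unfolded protein calls ended with DESeq2 size factors (adjusted p = 0.0608 and 0.0666). ALYREF, lower in HCC-LM3 knockout, went from 11.7 ± 0.949 to 516 ± 19 CPM (5.47, SE 0.13, adjusted p = 3.45e-26, n = 3). Of 16537 genes, 12399 passed edgeR's test, 5247 higher and 7152 lower, and 9313 had an absolute log2 fold change of at least 1 (3542 higher, 5771 lower). The split depends on the scaling. With DESeq2 size factors, which moved the median gene by 0.44, 6511 were higher and 5853 lower. With library totals alone, which moved it by −1.11, 1993 were higher and 10795 lower. It was 5550 and 4264 with GC and length offsets, which put the median gene at 0.15 in place of −0.21.

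The composition of the Huh-7 libraries moved with genotype. The 10 most abundant genes took 13% ± 0.48 of counts in wild type and 18.8% ± 0.13 in knockout. The next values cover only counts of protein-coding genes outside the mitochondrial genome. Their mean transcript length went from 1191 ± 14.8 to 968 ± 2.78 bases. The share of these counts from genes under 42% GC went from 3.51% ± 0.20 to 0.99% ± 0.05 (SD, n = 3). Across 16480 genes, which are not independent replicates, the log2 fold changes had Spearman correlations of 0.49 with GC content and −0.55 with length, against 0.53 and −0.09 in HCC-LM3. GC content and length together accounted for 38.1% of the variance of log2 fold changes in Huh-7 and for 15.3% in HCC-LM3. Of the Huh-7 calls, 7839 stayed with the same sign once GC and length offsets were used, and 785 turned.

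**Figure D4:**
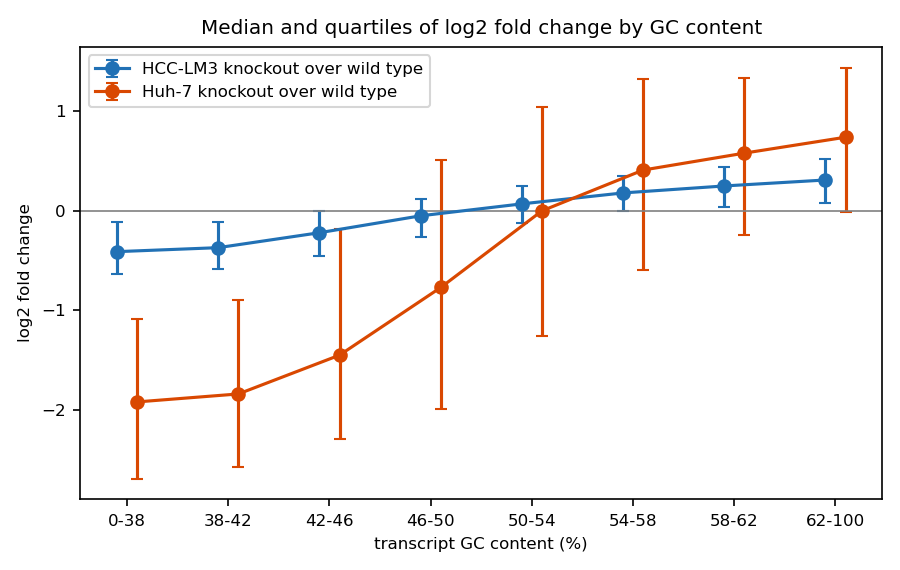
Median log2 fold change of knockout over wild type (vertical axis) in bins of transcript GC content (horizontal axis, %) for each line, with the quartiles of the genes in each bin. The medians go from −0.41 to 0.31 in HCC-LM3 and from −1.92 to 0.74 in Huh-7.

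Among the single genes of Huh-7, CMC1 rose by 3.70 (SE 0.17, adjusted p = 5.52e-19) and the iron hormone hepcidin gene HAMP by 3.41 (SE 0.16, adjusted p = 2.14e-18), from 4.5 to 47.7 CPM. The natriuretic peptide NPPB rose by 3.25, the alcohol dehydrogenase ADH4 by 3.23, FMC1 by 2.79, TMEM191B by 2.77 and neuromedin B (NMB) by 2.76. On the lower side, the RNA-binding protein PRRC2C fell by 5.14 (SE 0.16, adjusted p = 1.72e-21) and the corepressor scaffold SIN3A by 5.07 (SE 0.22, adjusted p = 1.85e-19). The endocytic receptor LRP2, SULT1B1, FSIP2, NMNAT3 and HNRNPUL2 fell as well, with −4.95, −4.84, −4.79, −5.88 and −5.29. Offsets for GC content and gene length kept all of these calls but moved several values: CMC1 was then at 6.01, HAMP at 1.75, NPPB at 1.80, TMEM191B at 1.55 and NMB at 1.37. PRRC2C was at −2.92, LRP2 at −2.60, SULT1B1 at −2.47 and FSIP2 at −1.78. FMC1-LUC7L2, a readthrough gene that overlaps FMC1 and LUC7L2, was at 0 in the knockout and at least 40.1-fold lower. Its level and those of FMC1, HNRNPUL2, NMNAT3 and SIN3A, which overlap other annotated genes on their strand, are uncertain, and ADH4 and FSIP2 overlap genes on the other strand.

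All 32 small-subunit ribosomal protein genes and 45 of 46 large-subunit genes rose and none fell, the same adjusted over the list alone. Their medians were 2.12 and 2.05 (adjusted p = 9.98e-22 and 7.61e-26, and adjusted p = 0.22 for each with an estimated correlation), and 1.13 and 1.23 with GC and length offsets. They were 1.01 and 0.94 with library totals alone, where 30 and 40 rose and 2 and 3 fell. RPS29 rose by 2.74, RPS27 by 2.69 and RPL35 by 2.64, and the offsets put the last pair at 1.25 and 0.95. Of 48 nuclear genes of oxidative phosphorylation, 40 rose and 6 fell, the same over the list alone (median 1.58, adjusted p = 9.32e-15, and adjusted p = 0.237 with an estimated correlation), with NDUFA4 at 2.48 and COX6A1 at 2.42. The median was 0.79 with GC and length offsets and 0.47 with library totals alone, where 32 rose and 10 fell. Of 33 antioxidant and ferroptosis genes, 20 rose and 9 fell, the same over the list alone (median 0.61, adjusted p = 0.00452, and adjusted p = 0.233 with an estimated correlation). The ferritin light chain FTL rose by 2.54, GPX1 by 2.23 and GPX4 by 2.21. The offsets put these genes at 1.22, 0.75 and 0.66, the list's median at 0.40 and COX6A1 at 1.25. With library totals alone the median of this list was −0.10 and its call ended (adjusted p = 0.0828, range over 16 alternatives 0.00124 to 0.0828). Histones rose in 28 of 32 cases, the same over the list alone (median 1.86, adjusted p = 2.97e-05, and adjusted p = 0.156 with an estimated correlation), a call that ended with GC and length offsets (0.75, adjusted p = 0.0917, range 1.01e-06 to 0.0917).

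Triglyceride and lipoprotein genes went both ways. Of 29 members 18 rose and 5 fell, the same over the list alone (median 0.69, adjusted p = 0.0031, and adjusted p = 0.212 with an estimated correlation). APOB, the protein of low-density lipoprotein, fell by 4.24 (SE 0.12, adjusted p = 1.04e-21), GPAM by 3.49 and the lipid transfer protein MTTP by 2.28, while APOC1 rose by 2.40. Under GC and length offsets they were at −1.85, −1.37, −1.07 and 0.87. The call ended with GC and length offsets (0.25, adjusted p = 0.358) and with library totals alone, where the median was −0.37 (adjusted p = 0.056, range over 16 alternatives 0.00132 to 0.358).

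Of 35 extracellular matrix genes, some of them also fibroblast markers, 26 fell and 3 rose, the same over the list alone (median −1.74, adjusted p = 0.00012, and adjusted p = 0.212 with an estimated correlation). NID1 fell by 3.97, the fibrillin FBN1 by 3.74, VCAN by 3.46 and LAMB1 by 3.37. Summed fibroblast markers went from 40.4 to 5.38 CPM relative to library totals alone. Among 28 Wnt, YAP and Notch targets, 18 fell and 4 rose (18 and 5 adjusted over the list alone; median −1.10, adjusted p = 0.0241, and adjusted p = 0.22 with an estimated correlation). TEAD1 fell by 3.51 and RNF43 by 3.29. For the endoplasmic reticulum unfolded protein response, 17 of 24 fell and 7 rose, the same over the list alone (median −1.22, adjusted p = 0.0366, and adjusted p = 0.237 with an estimated correlation). SEL1L fell by 4.17, HSP90B1 by 3.17 and the chaperone HSPA5 by 3.08. The matrix, Wnt and unfolded protein medians were −0.83, −0.54 and −0.60 with GC and length offsets, where FBN1 was at −1.61, VCAN at −1.13, LAMB1 at −2.09, SEL1L at −1.89, HSP90B1 at −1.91 and HSPA5 at −1.76, and all 3 lists still passed (adjusted p = 2.26e-05, 0.012 and 0.0392), and −2.72, −2.20 and −2.33 with library totals alone. The Wnt and unfolded protein calls ended with DESeq2 size factors (adjusted p = 0.0608 and 0.0666; ranges over 16 alternatives 0.00319 to 0.0608 and 0.000166 to 0.0816). The latter also ended without any 1 of the 6 HCC-LM3 libraries, whose spread enters the shared fit (up to adjusted p = 0.0584).

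Of 31 genes of the m6A and rRNA methylation machinery, 22 fell and 8 rose, the same over the list alone (median −1.75 with METTL5 at its bound, adjusted p = 0.0131, and adjusted p = 0.156 with an estimated correlation). Without METTL5 itself, 21 of 30 fell and 8 rose (median −1.72, adjusted p = 0.0234, and adjusted p = 0.212 with an estimated correlation). IGF2BP3 fell by 3.69 and YTHDC2 by 3.03. Under GC and length offsets they were at −2.15 and −0.81 (adjusted p = 7.21e-07 and 0.0375; the latter is the highest of 23 alternatives, of which the lowest gave 1.19e-26). Mitotic genes fell in 24 of 36 cases and rose in 7, the same over the list alone (median −1.19, adjusted p = 0.0234, and adjusted p = 0.233 with an estimated correlation), with NDC80 at −3.25 and MKI67 at −3.05 (−1.06 with the offsets). DNA replication genes fell in 25 of 41 cases and rose in 8 (25 and 9 adjusted over the list alone; median −0.71, adjusted p = 0.0385, and adjusted p = 0.364 with an estimated correlation), with MCM10 at −3.41. All 3 calls ended with GC and length offsets, at medians of −0.38, −0.07 and −0.36 (adjusted p = 0.311, 0.927 and 0.0843; lowest of 16 alternatives 0.000166, 0.000864 and 1.01e-06). The DNA replication call also ended without HCC-LM3 wild-type replicate 1, 2 or 3 or knockout replicate 1 or 2, with adjusted p up to 0.0628, and with DESeq2 size factors (adjusted p = 0.195), where the mitotic call ended as well (adjusted p = 0.0666).

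The other 18 lists did not pass the test in Huh-7 with TMM scaling and all libraries, although most of their members differed. For fatty acid uptake and acyl-CoA activation, 10 of 19 rose and 8 fell (adjusted p = 0.676). For beta-oxidation, 13 of 32 rose and 13 fell (13 and 14 adjusted over the list alone; adjusted p = 0.471), for fatty acid synthesis 11 and 15 of 27 (adjusted p = 0.518), with FASN at −2.30 and ACACA at −2.08 (−1.50 and −0.23 with GC and length offsets), and for cholesterol synthesis 12 and 11 of 25 (adjusted p = 0.377). ACSL4 fell by 2.33 (SE 0.18, adjusted p = 6.91e-12), ACSL3 by 2.53 (SE 0.14, adjusted p = 2.18e-17), ACSL1 by 2.08 (SE 0.22, adjusted p = 3.27e-10) and ACSL5 by 1.70 (SE 0.28, adjusted p = 2.18e-06). With GC and length offsets ACSL3 was at −1.05, ACSL1 at −1.41 and ACSL4 at −0.40 (adjusted p = 0.0214), and ACSL5 no longer passed (−0.48, adjusted p = 0.167, the highest of 23 alternatives, of which the lowest gave 1.01e-09).

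Numbers that rose and fell were 15 and 38 of 56 ribosome biogenesis factors (adjusted p = 0.0635), 17 and 25 of 45 translation factors (adjusted p = 0.488), 16 and 13 of 34 integrated stress response genes (adjusted p = 0.265) and 8 and 11 of 24 p53 targets (adjusted p = 0.756). Epithelial genes had 9 and 10 of 23 (adjusted p = 0.896), with E-cadherin (CDH1) at −4.06, mesenchymal genes 6 and 10 of 25 (adjusted p = 0.756), with fibronectin (FN1) at −4.37 (−2.79 with GC and length offsets), and hepatocyte genes 16 and 13 of 34 (adjusted p = 0.519). Xenobiotic genes had 11 and 9 of 25 (11 and 10 adjusted over the list alone; adjusted p = 0.197), hypoxia and glycolysis genes 16 and 12 of 37 (adjusted p = 0.279; 15 and 11 of 33 and adjusted p = 0.244 without ENO1, LDHA, PKM and TPI1) and interferon-stimulated genes 20 and 13 of 40 (adjusted p = 0.11). NF-kappaB genes had 13 and 6 of 27 (adjusted p = 0.0661), immediate early genes 9 and 11 of 24 (adjusted p = 0.756), apoptosis regulators 10 and 12 of 30 (adjusted p = 0.596) and mitochondrially encoded mRNAs 9 and 3 of 13 (adjusted p = 0.0635). Adjusted over the list alone the counts of these lists were the same where no others are given. Under library totals alone, more members fell than rose in all 18 lists, where 9 had more risen than fallen before: 3 and 14 for fatty acid uptake, 8 and 14 for cholesterol synthesis, 5 and 23 for the integrated stress response, 4 and 22 for hepatocyte and 3 and 13 for xenobiotic genes. The others of these were hypoxia and glycolysis with 4 and 24, interferon-stimulated genes with 7 and 21, NF-kappaB genes with 6 and 11 and mitochondrially encoded mRNAs with 3 and 8. The same totals called the ribosome biogenesis, translation factor and fatty acid synthesis lists as lower (adjusted p = 0.00145, 0.00264 and 0.0234; highest of 16 alternatives 0.275, 0.766 and 0.975). Xenobiotic genes passed as higher with GC and length offsets (adjusted p = 0.0365, range 0.0365 to 0.31) and mitochondrially encoded mRNAs with DESeq2 size factors (adjusted p = 0.0276, range 0.0276 to 0.859). Ribosome biogenesis passed as lower without knockout replicate 1 (adjusted p = 0.049), wild-type replicate 1 (0.0397) or wild-type replicate 3 (0.0409). Mitochondrially encoded mRNAs passed as higher without knockout replicate 1 or 3 (adjusted p = 0.049 and 0.0437) or wild-type replicate 1 or 3 (0.0376 and 0.0442). In 11 of the 18 lists the signs of the median, the mean and the test were not all the same.

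The third question was what the knockouts of both lines had in common. The stress cytokine GDF15, the adaptor SHC2, the linker histone H1-2 and GFUS, which makes GDP-fucose, were higher in both, and the nuclear import receptor KPNA2 and FNBP1L were lower in both. In all, 1112 genes rose in both lines, where independent lists of these sizes would share 732.3 (Fisher's exact test, two-sided, odds ratio 2.27, adjusted p = 6.54e-71), and 1644 fell in both, where 922.1 were expected (odds ratio 5.44, adjusted p = 9.93e-255). A further 950 passed the test in both lines with opposite signs. The log2 fold changes had a Pearson correlation of 0.19 across genes. Genes are not independent replicates, so neither this correlation nor the Fisher p-values given here measure replication. With GC and length offsets 644 genes rose in both (506.7 expected, odds ratio 1.54, adjusted p = 2.29e-14), 445 fell in both (374.8 expected, odds ratio 1.3, adjusted p = 1.43e-05) and the correlation was 0.02. Genes that rose and fell in both numbered 1483 and 1355 with DESeq2 size factors and 215 and 2838 with library totals alone. The number with 1 sign in both lines was 2756, 4337 without HCC-LM3 wild-type replicate 1, 1684 without wild-type replicate 2, 1616 without wild-type replicate 3 and 1781 without HCC-LM3 knockout replicate 3.

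Shared changes were ranked among called protein-coding genes with a mean of at least 5 CPM and no overlap of values in each line. Those with the largest increase included SHC2 (1.16 in HCC-LM3 and 1.44 in Huh-7), H1-2 (1.06 and 2.14), ITGB4 (1.03 and 1.10), GFUS (1.02 and 1.94) and GDF15 (0.95 and 1.47). Offsets for GC content and gene length put the Huh-7 values at 1.01 for SHC2, 0.59 for H1-2, 0.82 for GFUS and 0.23 for GDF15 (adjusted p = 0.0249, the highest of 23 alternatives, of which the lowest gave 5.65e-36). In Huh-7, with library totals alone, ITGB4 had −0.012 (adjusted p = 0.946, lowest of 23 alternatives 5.09e-23). The largest shared decreases among the genes so ranked were in LRRC58 (−1.40 and −1.69), KIAA1143 (−1.21 and −1.11), EXOC5 (−1.04 and −2.58), KPNA2 (−1.02 and −1.49), FNBP1L (−1.01 and −2.13) and TXLNG (−1.0 and −1.85). Genes under the level limit, such as METTL5, were not ranked. In Huh-7, KPNA2 and FNBP1L were at −0.71 and −1.22 with the offsets, and FNBP1L in HCC-LM3 at −0.67. LRRC58 and KIAA1143 had the opposite sign in Huh-7 with GC and length offsets (0.80 and 0.91, adjusted p = 0.00503 and 5.35e-05), and EXOC5 and TXLNG did not pass there (−0.02 and −0.03, adjusted p = 0.984 and 0.933, lowest of 23 alternatives 9.49e-38 and 5.77e-22). SHC2, ITGB4, GDF15, EXOC5, FNBP1L and TXLNG overlap other annotated genes.

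Whether the knockout acted differently in the 2 lines was tested as an interaction, the HCC-LM3 effect minus the Huh-7 effect. ALYREF and CMC1 fell in HCC-LM3 and rose in Huh-7, with differences of −9.60 (SE 0.18, adjusted p = 2.02e-29) and −6.98 (SE 0.24, adjusted p = 4.02e-21). The differentiation inhibitor ID3 had −0.50 in HCC-LM3 and 2.60 in Huh-7 (difference −3.10). ZFHX3 had 0.56 and −4.58 (difference 5.14), TAPBP, the peptide-loading protein tapasin, 0.51 and −4.59 (difference 5.10) and the zinc finger gene ZNF292 1.00 and −3.50 (difference 4.51). In HCC-LM3, TAPBP did not pass with GC and length offsets (0.25, adjusted p = 0.127) or without wild-type replicate 2 or 3 (adjusted p = 0.0583 and 0.0731, range over 23 alternatives 3.07e-05 to 0.127). ZNF292 did not pass there without wild-type replicate 2 (adjusted p = 0.0509, lowest of the alternatives 2.61e-08), nor ZFHX3 with library totals alone (0.40, adjusted p = 0.0512, lowest 5.46e-05). Offsets for GC content and gene length put the differences at 3.17 for ZFHX3, 2.10 for ZNF292 and −1.96 for ID3. ZNF292 was then at −0.85 in Huh-7 (adjusted p = 0.0447, the highest of 23 alternatives, of which the lowest gave 3.56e-48), ZFHX3 at −2.72 and ID3 at 1.30. ZFHX3 overlaps 16 annotated genes, 6 of them on its strand, and ZNF292 overlaps 2, so their levels are uncertain. In all, 10186 of 16537 genes differed, 6233 with the higher log2 fold change in HCC-LM3 and 3953 with the lower. The split was 4893 and 5103 with DESeq2 size factors, which moved the median difference by −0.41, and 9504 and 1574 with library totals alone, which moved it by 0.95. It was 3573 and 4498 with GC and length offsets. ACSL4 had a difference of 1.81 (SE 0.23, adjusted p = 1.79e-07), and 0.14 (adjusted p = 0.56) with those offsets.

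Of the lists, 10 had a called difference at the preset correlation. With an estimated correlation none of the 10 passed (lowest adjusted p = 0.254), and 4 of the 30 lists had an unadjusted p under 0.05. Small-subunit and large-subunit ribosomal proteins had median differences of −1.97 and −1.93 (adjusted p = 7.25e-26 and 1.99e-30), with 32 of 32 and 45 of 46 members lower, and oxidative phosphorylation −1.45 (41 of 48 lower, adjusted p = 5.87e-18). Extracellular matrix genes had 1.77 (25 of 35 higher, adjusted p = 0.000342), Wnt, YAP and Notch targets 1.29 (17 of 28 higher, adjusted p = 0.00785), the unfolded protein response 1.41 (17 of 24 higher, adjusted p = 0.0173) and DNA replication genes 0.73 (27 of 41 higher, adjusted p = 0.0132). Antioxidant genes had −0.37 (17 of 33 lower, adjusted p = 0.0132). The m6A and rRNA methylation machinery had 1.57 (20 of 31 higher, adjusted p = 0.031) and histones −1.24 (19 of 32 lower, adjusted p = 0.0132). Without METTL5 itself, the methylation list had 1.60 (20 of 30 higher, adjusted p = 0.0247). Offsets for GC content and gene length left the first 8 lists called, at median differences of −1.02, −1.04, −0.79, 0.65, 0.70, 0.60, 0.29 and −0.23 in the order given. Their medians were −1.01, −0.96, −0.49, 2.59, 2.24, 2.36, 1.68 and 0.48 with library totals alone. With GC and length offsets the calls of the last pair of lists ended (adjusted p = 0.676 and 0.93), as they did without HCC-LM3 wild-type replicate 1 (adjusted p = 0.0531 and 0.0711; lowest of 16 alternatives 0.00155 and 0.000896). With DESeq2 size factors the methylation, unfolded protein and replication calls ended (adjusted p = 0.085, 0.0655 and 0.116; the unfolded protein range was 0.000186 to 0.077 and the replication range 1.18e-07 to 0.116). With library totals alone the antioxidant call ended (adjusted p = 0.119, range 0.00512 to 0.119), and without HCC-LM3 wild-type replicate 3 the unfolded protein call (adjusted p = 0.06). For the integrated stress response (adjusted p = 0.824), mitotic (adjusted p = 0.252), mesenchymal (adjusted p = 0.296), cholesterol (adjusted p = 0.0999) and ribosome biogenesis lists (adjusted p = 0.288) no difference between the lines was called with TMM scaling. Library totals alone called the integrated stress response, mitotic and ribosome biogenesis lists as higher in HCC-LM3 (adjusted p = 0.0142, 0.0248 and 0.0141; highest of 16 alternatives 0.966, 0.776 and 0.777). The cholesterol list was called as lower in HCC-LM3 with GC and length offsets (adjusted p = 0.00492) and with DESeq2 size factors (adjusted p = 0.038, highest of 16 alternatives 0.741). Library totals alone also called fatty acid synthesis, translation factors, immediate early genes and, as lower, xenobiotic genes (adjusted p = 0.0348, 0.00489, 0.00768 and 0.0342; highest of 16 alternatives 0.93, 0.926, 0.655 and 0.691). Immediate early genes were called with GC and length offsets as well (adjusted p = 0.028).

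**Figure D5:**
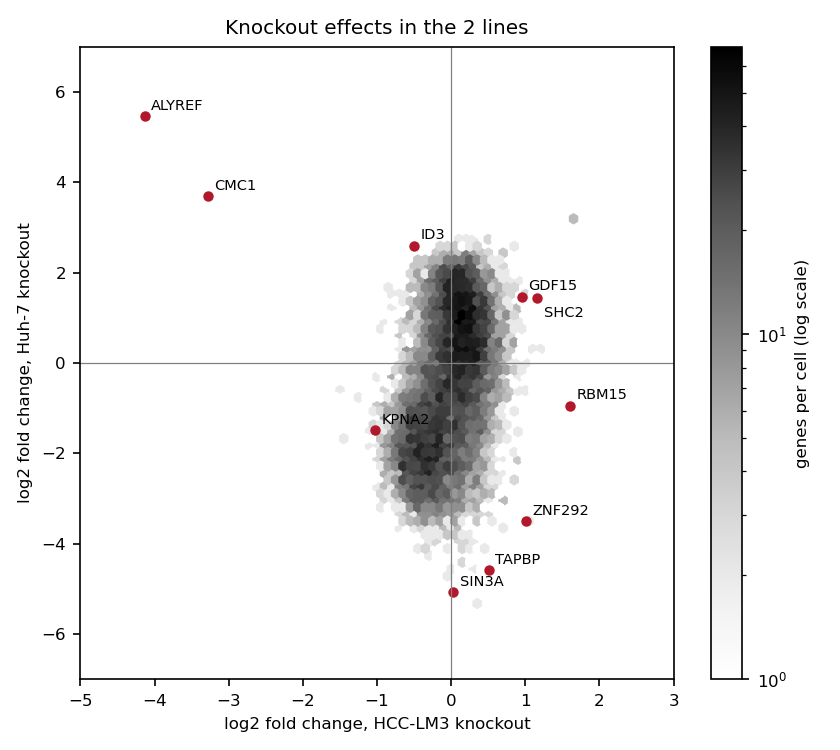
Log2 fold change of knockout over wild type in Huh-7 (vertical axis) against HCC-LM3 (horizontal axis) for 10991 genes with a mean of at least 1 CPM in each line, METTL5 left out; shading gives the number of genes per cell, red points are single genes and 5 genes lie outside the range. ALYREF and CMC1 sit at the upper left (−4.13 and 5.47; −3.28 and 3.70), and KPNA2 and SHC2 have the same sign in both lines.

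The wild-type lines were compared as background. Genes of the hepatocyte list were mostly higher in Huh-7. Of 34 hepatocyte genes 31 were higher in Huh-7 and 2 in HCC-LM3, with median levels of 170 and 0.038 CPM. SERPINA1, APOB and TTR stood at 5562 ± 190.8, 1031 ± 68.1 and 664.7 ± 46.3 CPM in Huh-7 and at 0 counts in HCC-LM3, at least 58500-fold, 10840-fold and 6991-fold lower. APOA1 was at 2684 CPM in Huh-7 and 0.0106 in HCC-LM3. INS-IGF2, which overlaps IGF2, was at least 12840-fold lower in HCC-LM3, and its level is uncertain. In the other direction, PXDN, KRT7, BASP1, KIF26A and CCN5 were at 336, 267, 256, 230 and 216 CPM in HCC-LM3 and at 0 counts in Huh-7, at least 2210-fold, 1758-fold, 1683-fold, 1512-fold and 1423-fold lower. Interferon-stimulated genes were higher in HCC-LM3 in 30 of 40 cases (median 14.1 against 2.53 CPM) and hypoxia and glycolysis genes in 25 of 37. Without ENO1, LDHA, PKM and TPI1 the latter were higher in HCC-LM3 in 24 of 33 cases (87.2 against 10.8 CPM). Triglyceride and lipoprotein genes were higher in Huh-7 in 25 of 29 cases. In all, 13685 of 16537 genes differed, 6910 higher in HCC-LM3 and 6775 higher in Huh-7. With library totals alone, which moved the median gene by 0.42, the numbers were 8430 and 5429.

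Markers of other cell types were measured as a check of the cultures, as sums of CPM relative to library totals alone. Leukocyte markers summed to 60.5 in HCC-LM3 wild type, 73.2 in its knockout, 73.7 in Huh-7 wild type and 55 in its knockout. Fibroblast markers summed to 59.8, 46.8, 40.4 and 5.38, endothelial markers to 3.47, 4.66, 15 and 3.16, cholangiocyte and progenitor markers to 427, 472, 680 and 871, and neuronal and embryonic kidney markers to 11.7, 8.93, 50 and 3.77. No test was run on these sums. Single genes made up most of several of them. In Huh-7 wild type, LIN28B stood at 49.8, PECAM1 at 14.3, KRT19 at 524 and CD68 at 48.4. In HCC-LM3 wild type, KRT7 stood at 382 and CD68 at 59.2. The leukocyte gene PTPRC was at 0 in HCC-LM3 and 0.013 in Huh-7 wild type.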

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

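The tests of GC and length offsets, library totals alone, thinning, abundant genes, the expected count of METTL5, its pseudogenes, SSB and neighbours, swapped labels and genes overlapping ALYREF and CMC1 were chosen only after the results were seen, and the regroupings before. What drew attention here is that the knockout effect differed between HCC-LM3 and Huh-7 by the interaction test.

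In Huh-7, 12399 of 16537 genes passed the test, against 4440 in HCC-LM3, and 10186 differed between the lines. A difference in depth as the cause is argued against by the 12126 genes called after thinning every library to the lowest total. Abundant genes taking up the counts are argued against as the whole cause by the 1993 genes called higher with library totals alone, where a common dilution would lower all others; the 12437 genes called without the 50 most abundant add little, since TMM scaling already trims such genes. A GC and length trend of the form the offsets fit is argued against as the whole cause by 7839 calls kept with their sign. With offsets 785 other calls turned and 3735 were lost. After the offsets, Huh-7 log2 fold changes still had correlations of 0.09 with GC content and −0.12 with length, so kept calls may hold some trend. A trend of another form was not tested. Open stay an effect of METTL5 loss, an effect of the guide treatment, a difference between clones and a difference in RNA quality or library preparation. The labels name no control guide, clone or batch to part these, and library composition moves with genotype in Huh-7.

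METTL5 at 0 counts in all 6 knockout libraries is another pattern, since a guide-made frameshift alone leaves a transcript that can still be counted. Low depth is argued against by the lowest expected count of 52.3. Reads counted under METTL5 pseudogenes or the overlapping SSB are argued against by their sum, which changed by −5.35 CPM in HCC-LM3 and −20.9 in Huh-7, where METTL5 lost 8.99 and 9.51, and in Huh-7 knockout SSB stood at 4.54, 2.68 and 2.09 CPM. Loss of every copy of a segment reaching both neighbours is argued against by their lowest knockout count of 19, in SSB. Loss of some copies was not tested and is not excluded. The neighbours SSB and UBR3 were lower in HCC-LM3 knockout (−0.55 and −0.88) and in Huh-7 knockout (−2.93 and −2.77). With GC and length offsets they were at −0.17 and −0.53 in HCC-LM3 and at −1.98 and −0.26 in Huh-7. Open stay loss of the METTL5 transcript itself, which may come from a deletion inside the gene or from decay, and a step of the upstream counting that left the gene at 0.

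ALYREF and CMC1 are the last pattern, with differences of −9.60 and −6.98. Swapped labels in 1 line are argued against by METTL5 at 0 in all 6 knockout libraries, if those zeros did not come from the upstream counting. Reads moving to an overlapping gene are argued against by at least 76.2% of the change staying in the sum of each gene with its partner. A fitted GC or length trend as the whole cause is argued against by a smallest absolute log2 fold change of 2.95 with offsets. Open stay a line-specific effect of METTL5 loss or of the guide treatment, a difference between clones, a difference in library preparation and a step of the upstream counting. The design does not separate these.

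The other opposite changes were ZFHX3 with a difference of 5.14, TAPBP with 5.10, ZNF292 with 4.51 and ID3 with −3.10, and with GC and length offsets 3.17, 5.59, 2.10 and −1.96. Of 267 genes that the rule for named genes took, 205 had a called difference between the lines, against 10186 of all 16537 genes (61.6%). The rule picked genes by their changes in these same data, so this share is no separate evidence of a difference. Among the lists the median differences were 1.57 for the m6A and rRNA methylation machinery, −1.97 and −1.93 for small-subunit and large-subunit ribosomal proteins, 1.41 for the unfolded protein response and 0.73 for DNA replication. They were −1.45 for oxidative phosphorylation, −0.37 for the antioxidant list, 1.77 for extracellular matrix, 1.29 for Wnt, YAP and Notch targets and −1.24 for histones.

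Regrouping the libraries asks how often other splits call as much. Within HCC-LM3, Huh-7 and the wild-type lines, the 10 splits of 6 libraries are too few for a share under 0.05. Only 1 of 10, the real one, reached the real gene counts of 4440, 12399 and 13685, and the highest of the others were 2, 0 and 0 in edgeR, with 207 to 3003, 201 to 285 and 18 to 323 genes at an unadjusted p under 0.05. For lists the real counts of 13 and 12 were reached by 1 of 10 splits each, with the highest others at 10 and 9. The medians of the others were 7 and 6, so splits that mix the genotypes often called lists too. With both lines regrouped, 60 of 200 splits were drawn. For genes that changed alike in both lines, 1 of 60 reached 2756 (highest other 1), and for the difference between lines 1 of 60 reached 10186 (highest other 9956, from draws that kept Huh-7 parted by genotype). Since other splits of a knockout comparison call at most 2 genes, these draws exclude chance only against no effect of genotype at all. They test neither sharing, for which independent lists would give 732.3 and 922.1 genes, nor a difference between lines. For the lists that differ between lines, 7 of 60 splits reached the real 10 (highest other 14), so chance cannot be excluded; the 51 draws that part neither line by genotype called up to 11 lists.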

How the results depend on the processing

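GC and length offsets, library totals alone, thinning, leaving out the 50 most abundant genes, the lists without METTL5 and the hypoxia list without ENO1, LDHA, PKM and TPI1 were tests chosen only after the results were seen. Recomputing 307 gene values over 23 settings gave 7013 values. Of these, 6808 kept their side of the threshold, 196 lost their call, 2 gained one and 7 had the opposite sign, and the cause was not tested. The rule counted a sign change between uncalled values, or a value without an adjusted p, among the 6808. With GC and length offsets the calls were 2950 in HCC-LM3 and 1089 alike in both lines, and in Huh-7 LRRC58 (0.80) and KIAA1143 (0.91) were called higher in place of lower (adjusted p = 0.00503 and 5.35e-05). HMGCS1 (0.091), SLC7A11 (0.36), MDM2 (0.18) and PARP14 (0.25) had the opposite sign there but did not pass (adjusted p = 0.346, 0.217, 0.337 and 0.324), nor did ITGB4 in Huh-7 (−0.012, adjusted p = 0.946) with library totals alone. With those totals 16 lists differed between lines in place of 10. An absolute log2 fold change of at least 1 left 282 calls in HCC-LM3 and 108 alike in both lines, and an adjusted p under 0.01 left 2622 and 1603, by construction. With an estimated inter-gene correlation, camera called 1 list in HCC-LM3, 0 in Huh-7 and 0 for the difference (6, 5 and 4 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 16, 27 and 24. Without METTL5 in its list 12, 12 and 10 lists passed, and without the 4 glycolysis genes 13, 12 and 10. Among the called values of genes named for HCC-LM3 and for Huh-7 (139 and 150), 57 and 107 were over 1.5 times smaller with GC and length offsets, and 3 and 1 over 1.5 times larger. Library totals alone made 12 and 48 smaller and 0 and 19 larger by as much.

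Leaving out 1 library gave 2743 to 6136 calls in HCC-LM3 (lowest without wild-type replicate 3, 2832 without wild-type replicate 2, highest without wild-type replicate 1), 12013 to 12704 in Huh-7, 9847 to 10105 for the difference and 13387 to 14132 between the wild-type lines. Calls alike in both lines were 1616 to 4337 (1684 without HCC-LM3 wild-type replicate 2 and 1781 without HCC-LM3 knockout replicate 3), and lists 11 to 13, 10 to 14 and 8 to 10. HCC-LM3 wild-type replicate 1 stood apart, with chi-square per degree of freedom of 41.9 and 34.1 against its group and 2.8 to 19.6 in other pairs. Over the other settings with the 0.05 threshold, Huh-7 calls were 9814 to 13036. The replicate numbers did not pair the libraries: same-numbered pairs had r from −0.11 to 0.08, and 0 of 6 knockout libraries correlated best with their own number. With the replicate block there were 3988, 12251, 9962 and 2455 gene calls in HCC-LM3, in Huh-7, for the difference and alike in both lines, and 13, 10 and 8 lists. With the block the Huh-7 calls of the unfolded protein and DNA replication lists ended (adjusted p = 0.0816 and 0.0662), as did the differences of the methylation and unfolded protein lists (0.066 and 0.077). In simulated counts with these depths and spreads, 1.5-fold changes were recovered in 73.1% of cases in HCC-LM3 and 67.2% in Huh-7. The changed genes had a mean of at least 5 CPM, and depth was not varied. Thinned to the lowest library total, 4303 and 12126 genes were called.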

Other observations

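The levels of the nuclear RNAs and glycolysis genes given here were looked at only after values had been seen.

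The long nuclear RNAs of speckles and paraspeckles went down together in Huh-7 knockout. MALAT1 fell by 3.76 (SE 0.33, adjusted p = 4.57e-06), from 564 ± 33.4 to 41.4 ± 8.87 CPM, and NEAT1 fell by 4.02 (SE 0.33, adjusted p = 1.35e-06), from 54.2 ± 2.74 to 3.33 ± 0.204 (SD, n = 3, edgeR). With GC and length offsets, chosen after the result was seen, the values were −1.25 and −1.64 (adjusted p = 0.0039 and 0.000656). In HCC-LM3, MALAT1 had 0.90 (SE 0.28, adjusted p = 0.0476), from 290.2 ± 35.4 to 541 ± 246 CPM, with a wide spread in the knockout. Knockout replicate 2 stood at 826 CPM and the others at 401 and 397, so 1 library carried much of this rise. NEAT1 had −0.57 there (SE 0.21, adjusted p = 0.0765).

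Among glycolysis genes, group means of GAPDH lay between 7799 and 28860 CPM and ALDOA between 1405 and 5280, while ENO1 lay between 1.64 and 3.41, LDHA between 0.525 and 2.53, PKM between 0.678 and 7.22 and TPI1 between 0.856 and 18.1. These last genes have pseudogenes or many transcripts, and the group means of PKM in the deposited TPM were 522 to 2766, so their counts are uncertain. ENO1 in HCC-LM3 (−1.04, adjusted p = 0.0209) and LDHA in Huh-7 (−1.78, adjusted p = 0.0407) passed the test, with ranges over 23 alternatives of 0.000245 to 0.1001 and 1.34e-07 to 0.279. Without HCC-LM3 wild-type replicate 1 or 3 or knockout replicate 2 or 3 the ENO1 call ended, and the LDHA call under 17 alternatives. They are in the hypoxia and glycolysis counts, which are also given without these genes. GAPDH in Huh-7 wild type and knockout was at 8266 ± 687 and 28860 ± 667 CPM after TMM scaling, but at 7722 ± 388 and 8798 ± 66 in the deposited TPM (SD, n = 3), which carry no such scaling. ALDOA went from 2208 ± 38 to 5280 ± 111 CPM there but from 1902 ± 9.83 to 1474 ± 22.5 in the TPM, and PGK1 from 189 ± 14.4 to 366 ± 8.55 CPM but from 69.2 ± 6.3 to 39.7 ± 0.66 in the TPM. The TPM also differ from CPM in being scaled by length, and what makes these gaps was not tested.

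In wild-type cells, mitochondrially encoded mRNAs were higher in Huh-7 in 13 of 13 cases and histones in 26 of 32, and xenobiotic metabolism genes in 20 of 25.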
